A study of Danio rerio with 32 samples.

How the data were processed

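The 32 libraries were made from V2a interneurons of adult zebrafish carrying a green reporter, sorted by fluorescence into cells with (D) and without (G) a retrograde rhodamine dextran tracer, from uninjured fish and at 3 and 8 weeks after injury. Per the labels, libraries were made with a low-input full-length cDNA kit. The authors deposited 1 table of FPKM (fragments scaled to gene length and library total) with 42370 genes, of which 31901 have Ensembl IDs and 10469 were assembled outside the annotation. The submitters' processing notes name HISAT2 2.0.5, HTSeq 0.9.1 and the danRer11 build, without giving their roles or order. The gene lengths and library totals behind the FPKM are not in the table, and a genome was not used here, so no positions are given. In all, 29178 IDs had a symbol and 1719 symbols were shared by 2 or more IDs; for those the ID is given, since paralogues cannot be told apart by name. The samples were grouped by their labels into 6 groups, and every per-sample column was used.

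Low FPKM values fall on whole multiples of a step per gene and library. From these steps library totals of 9.42 to 27.7 M fragments were inferred, and fragments were recovered for 32463 of 38613 expressed genes. Of their values 99.973% were whole within 0.05, but gene lengths were picked to make values whole, so this share is not a check. The recovered fragments held only part of each library total, from 29.6% in D8W replicate 5 to 58.6% in Gcon replicate 5. These counts are inferred and serve only for depth and for 1 alternative. PCR duplicates were not removed on molecular identifiers, so depth limits cover counting error only.

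FPKM values were divided by a median-ratio factor per library, taken over 6387 genes at 1 FPKM or more in at least 28 libraries with a pseudocount of 0.1, and log2-transformed with a pseudocount of 1. Genes at 1 FPKM or more in at least 5 libraries were tested, 22552 in all, 17480 with a symbol. One limma model (version 3.58.1, R 4.3.3, trend and robust empirical Bayes) with a mean per group gave 9 pairwise comparisons and 2 interactions, each adjusted by Benjamini-Hochberg over all genes tested, with calls at an adjusted p under 0.05. All tests were two-sided. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Group levels are means and SD of deposited FPKM.

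In all, 31 gene lists fixed before the data were examined, with at least 5 tested members each, were tested with limma camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison. In 9 of the lists the preset test passed in 0 comparisons. Genes were named by a rule fixed before the data were examined. Among passing genes with a mean of at least 5 FPKM in the higher group, at least 1 FPKM in 3 of its libraries, medians differing the same way and a symbol that is not a clone name, it took the 8 highest and 8 lowest fold changes for D3W or D8W against Dcon and for D against G after injury, and 4 and 4 elsewhere. It added up to 4 members of each list with a passing test or member, the 3 smallest p where fewer than 3 genes passed, and a few genes fixed by name where discussed, among them SLC17A6, ATF3, gap43, SOX11 and STMN4. Some genes that the rule took are not reported here.

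The method was tested on simulated data for D3W against Dcon, with 10 simulations of 200 changed genes drawn from genes with a mean log2 value above 2. For these, deviations from the group means were reshuffled over all 32 libraries and the changes were added in D3W. It recovered 1% of changes of 1 log2, 20.3% of 2 and 77.3% of 4, and 5.4% of its calls were false. In simulations without changes 4.98% of p-values were under 0.05 and 0 simulations had calls. The reshuffling does not keep the spread of the D3W libraries in D3W, so these rates need not hold for the real comparison. Alternatives fixed before the data were examined were another pseudocount, no filter, FPKM as deposited, quantile normalization, array weights, only the groups compared, a replicate block, a fold threshold, an estimated correlation and leaving out each library in turn. Added after seeing the data were the number of detected genes as a covariate, leaving out both libraries with fewest genes, and limma voom on the recovered fragments of 21948 tested genes. Overlaps of comparisons that share controls were compared with simulated unchanged groups and with splits of the controls into 2 parts. All such splits were used, each in both directions, which gave 20 fits that overlap in their libraries.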

Results

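V2a interneurons are excitatory spinal neurons that drive locomotion. RNA was sequenced from V2a interneurons sorted by their green reporter from adult zebrafish spinal cord segments 1 to 7, from uninjured fish and from fish 3 or 8 weeks after a spinal cord injury. A rhodamine dextran tracer taken up by axons and carried back to the cell body split the reporter-positive cells. Cells with tracer are called D here; per the labels they are retrogradely traced neurons in uninjured fish and neurons with a regrown axon after injury. Cells without tracer are called G. There were 6 libraries of uninjured G cells (Gcon), 5 of uninjured D cells (Dcon), 5 each of G3W, D3W and G8W, and 6 of D8W, where the number gives the weeks. Tissue from 20 fish was collected per condition. The labels do not say that the libraries of a group came from separate fish, so p-values measure only the spread between these samples, which may be technical.

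The deposited FPKM values keep the steps of whole fragments, from which 9.42 to 27.7 M fragments per library were inferred. A count of 3 fragments in a gene of 1 kb then equals 0.108 to 0.319 FPKM. Genes at 1 FPKM or more numbered 14670 ± 2466 in Gcon (SD, n = 6), 12624 ± 1481 in Dcon (n = 5) and 17233 ± 637 in G3W (n = 5). They numbered 12228 ± 3773 in D3W (n = 5), 15730 ± 2344 in G8W (n = 5) and 13838 ± 2253 in D8W (n = 6). Replicates 3 and 5 of D3W had 7755 and 8710 such genes, and the other 30 libraries had 10929 to 18414. The 13 protein genes of the mitochondrial genome held 7.09% ± 2.46 of FPKM in Gcon, 10.5% ± 2.37 in Dcon and 7.97% ± 2.19 in G3W. They held 17.3% ± 5.90 in D3W, 11.1% ± 4.1 in G8W and 18.1% ± 5.67 in D8W. Fold changes below are on the log2(FPKM + 1) scale, which understates changes of low genes. The median fold change of all genes moved with the scaling by over 0.1 log2 in several comparisons; for D3W against G3W it was -0.26, against -0.58 with FPKM as deposited and 0.01 after quantile normalization.

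**Figure D1:**
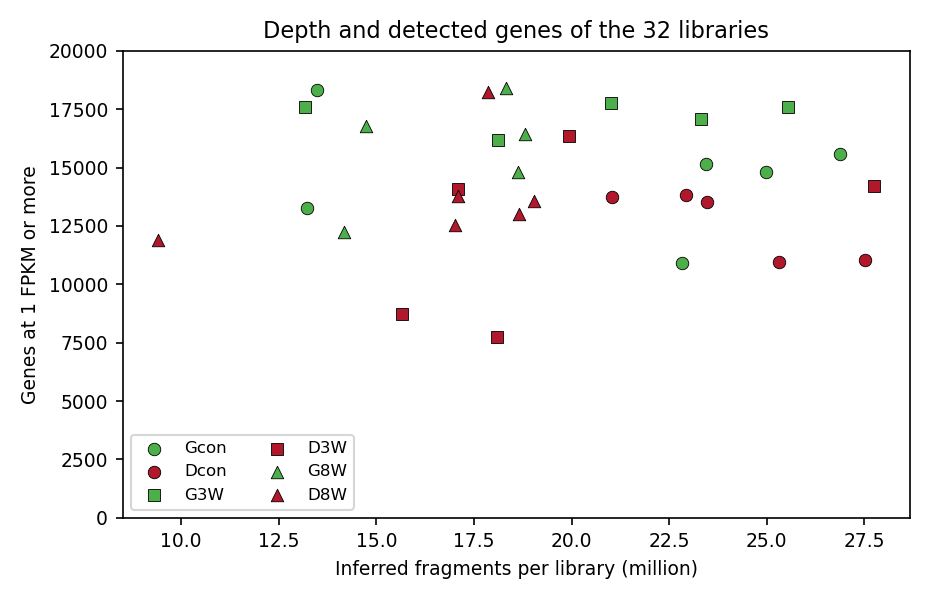
Each point is 1 of the 32 libraries, with inferred fragments (M) on the x axis and the number of genes at 1 FPKM or more on the y axis; colour gives the sort (green G, red D) and shape the condition. D3W replicates 3 and 5 lie lowest, at 7755 and 8710 genes.

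**Figure D2:**
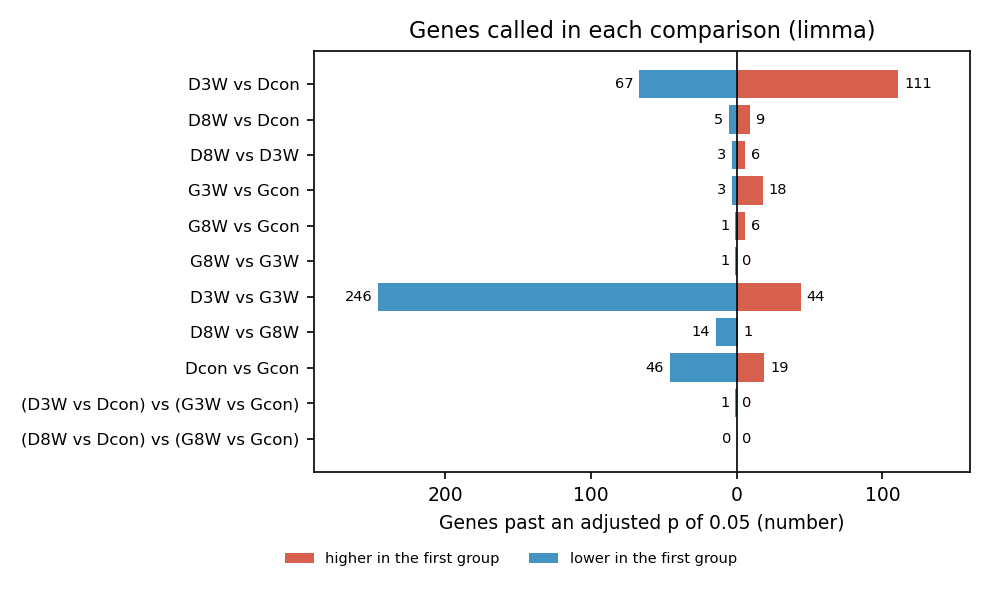
Bars give the number of genes past an adjusted p of 0.05 (limma) in each comparison, to the right for genes higher in the first group and to the left for genes lower in it. D3W against G3W had 246 lower and 44 higher genes, and D3W against Dcon 111 higher and 67 lower.

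The first question was how V2a neurons that had regrown an axon by 3 weeks differed from traced neurons of uninjured fish (D3W against Dcon, n = 5 each). The S100 family genes icn (ENSDARG00000009978) and s100a10b (ENSDARG00000025254) rose most, by 7.57 (SE 1.05, limma adjusted p = 0.00043) and 7.03 (SE 0.937, adjusted p = 0.000157). The level of icn was 28.8 ± 34 FPKM (SD) in Dcon and 1630 ± 879 in D3W, with every D3W library above every Dcon library. That of s100a10b was 10.9 ± 19.1 and 658 ± 597. Cells without tracer held both genes too. icn was at 545 ± 458 FPKM in Gcon and 1970 ± 1370 in G3W, and s100a10b at 88.6 ± 73.6 and 328 ± 165. High levels are thus not particular to neurons with a regrown axon. S100B, a glial calcium-binding gene, rose by 5.78 (SE 1.12, adjusted p = 0.00832). crlf1a, which codes for a cytokine receptor-like factor, rose by 5.20 (SE 0.890, adjusted p = 0.00255), and the sodium channel gene scn4ab by 4.31 (SE 0.743, adjusted p = 0.00258). CDK5R1 (ENSDARG00000037916), which codes for the neuronal activator of CDK5, fell by 3.90 (SE 0.763, adjusted p = 0.00886). These calls, and those of TCIM (ENSDARG00000076858, 6.18), rgl3a (5.11) and the p53 target rps27l (3.88), held whichever library was left out. Those of icn, TCIM, crlf1a and rgl3a held in the other alternatives as well, though limma voom did not cover icn. With voom s100a10b lost its call (adjusted p = 0.175), as did S100B (0.423, and 0.129 without the 2 libraries with fewest genes) and scn4ab, which also lost it with a replicate block (up to 0.107). CDK5R1 lost its call with only the 2 groups compared, with a block and without those 2 libraries (up to 0.135). rps27l lost it in these 3 and with voom (up to 0.122).

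Of 80 tested genes for cytosolic ribosomal proteins, 12 rose over all genes and 68 when adjusted over the list alone. In all 78 of them had a positive fold change and the median was 1.31 (camera adjusted p = 7.21e-43; adjusted p = 0.261 with an estimated correlation). Of the 12, the naming rule took rps27l, given above, and 3 whose calls depended on single libraries. rps27.1 lost its call without Dcon replicate 2 or D3W replicate 4 or 5 (adjusted p up to 0.0814), RPS26 (ENSDARG00000037071) without Dcon replicate 2 or 4 or D3W replicate 3, 4 or 5 (up to 0.0928), and RPL13 without Dcon replicate 1, 2, 3 or 4 or D3W replicate 3, 4 or 5 (up to 0.106). All 3 also lost it with only the 2 groups compared, with a replicate block and without the 2 libraries with fewest genes (up to 0.219, 0.318 and 0.396). The 13 mitochondrial genome genes had a median of 0.89, with 0 past the test over all genes and 9 higher adjusted over the list alone (camera adjusted p = 2.73e-08; adjusted p = 0.261 with an estimated correlation and 0.0609 after quantile normalization). Among 7 tested V2a and glutamatergic identity genes the median was -1.56, with 0 fallen over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00336; adjusted p = 0.261 with an estimated correlation). Lists of other cell types also passed. The median was 1.65 for 17 oligodendrocyte and Schwann cell markers (camera adjusted p = 0.000608) and 0.88 for 19 astroglia and ependymal markers (camera adjusted p = 0.00011). It was 1.01 for 15 endothelial and mural cell markers (camera adjusted p = 0.0107). Each had an adjusted p = 0.261 with an estimated correlation. In these 3 lists S100B alone passed over all genes, and 1, 6 and 0 genes were higher adjusted over the list alone, beside 1 lower astroglial gene. The synaptic vesicle list (39 genes) had a median of -0.49 and 0 genes past either test (camera adjusted p = 0.00336), and the potassium channel list (81 genes) one of -0.28 and 1 fallen gene by either count, KCNC1 (ENSDARG00000032959; camera adjusted p = 0.0107). Each had an adjusted p = 0.261 with an estimated correlation. Of these calls, the synaptic vesicle one was lost without D3W replicate 4 (0.0699), the potassium channel one without D3W replicate 3 or 4 (0.0538 and 0.0518) and the endothelial one without D3W replicate 4 (0.131). The oligodendrocyte call was lost with array weights (0.0563) and the potassium channel one also without the 2 libraries with fewest genes (0.0746). KCNC1 passed in single-library fits only without Dcon replicate 5 or D3W replicate 2 (adjusted p up to 0.102). At the preset correlation the apoptosis and p53, heat shock, and GABA and glycine receptor lists passed too. Their calls held in 15, 15 and 7 of 17 alternative fits.

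Of 39 growth cone and axon cytoskeleton genes 0 passed over all genes and 2 were lower adjusted over the list alone (camera adjusted p = 0.241). evlb, an actin regulator gene outside that list, fell by 3.70 (SE 0.938, adjusted p = 0.046), but passed in single-library fits only without D3W replicate 1 or 2 (up to 0.136). The growth cone gene gap43 was 382 ± 131 FPKM in Dcon and 401 ± 226 in D3W (0.32, SE 0.645, adjusted p = 0.907). The injury-induced transcription factor gene ATF3 was at 186 ± 188 and 135 ± 57.4 (0.22, SE 0.549, adjusted p = 0.932), where the means and the log2 fold change differ in sign. Both changed sign with FPKM as deposited, to -0.03 and -0.12, and after quantile normalization, to -0.03 and -0.05. The pair of SOX11 genes were at 0.99 and -0.23 (adjusted p = 0.498 and 0.952) and the pair of STMN4 genes at 0.41 and 0.85 (adjusted p = 0.782 and 0.527). Of 24 injury and regeneration transcription factors 0 passed over all genes and 2 were higher adjusted over the list alone (camera adjusted p = 0.149).

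In all, 111 genes rose and 67 fell of 22552 tested; 2815 had an unadjusted p under 0.05. With FPKM as deposited the split was 57 higher and 100 lower, and after quantile normalization 69 and 58. The count was 59 without D3W replicate 3 or 5, 79 without D3W replicate 4, and 338 and 570 without D3W replicates 1 and 2. It was 74, 67, 114 and 72 without Dcon replicates 1 to 4, and 20 without both libraries with fewest genes. Of 27 passing genes that the naming rule took, 11 kept their call in each of those single-library fits and 5 in every other alternative. With only the 2 groups compared the D3W against Dcon count was 15, while that of G3W against Gcon was 21. With array weights these counts were 85 and 112. The 178 calls thus depend on how the spread is estimated over the 6 groups. Whether D or G cells changed in more genes is not settled.

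**Figure D3:**
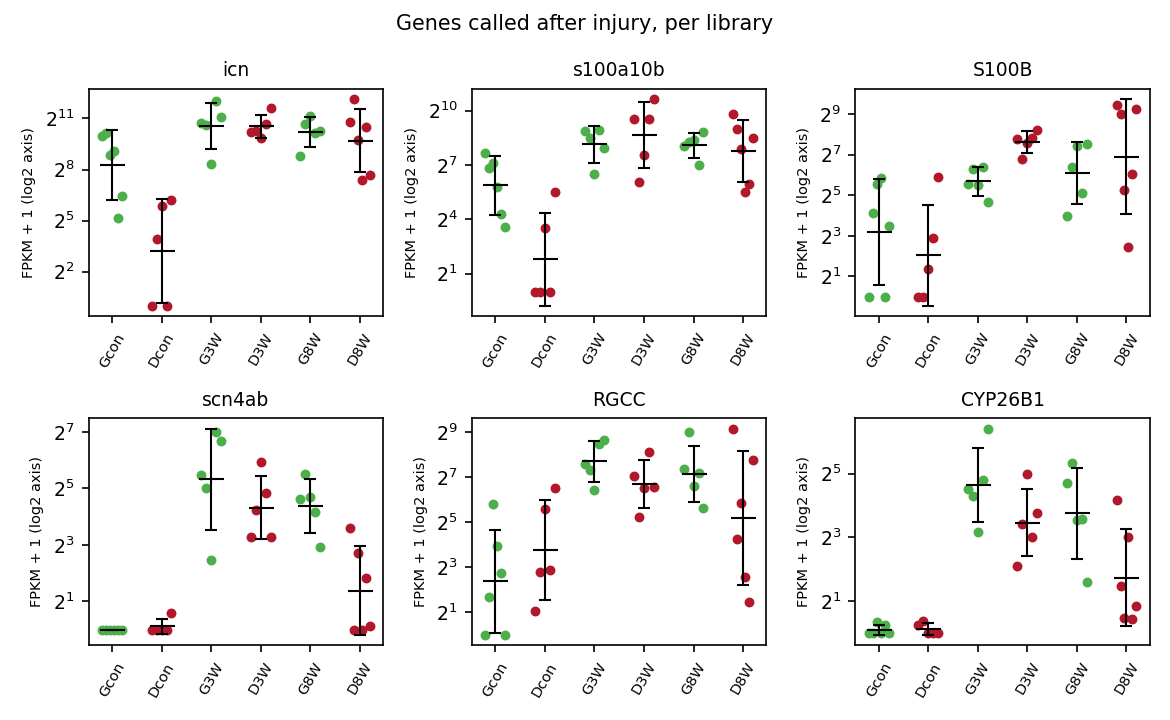
Each point is 1 library (green G, red D), with FPKM + 1 on a log2 axis; bars give the mean and SD of log2(FPKM + 1) per group, n = 5 or 6. For icn the Dcon libraries lie at 0 to 73.3 FPKM and the D3W libraries at 925 to 3130.

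At 8 weeks (D8W, n = 6, against Dcon, n = 5) the genes with the largest rise were again icn, by 6.82 (SE 1.01, adjusted p = 0.00148), and s100a10b, by 6.23 (SE 0.897, adjusted p = 0.000847). In D8W they stood at 1490 ± 1600 and 352 ± 322 FPKM, and in G8W, without tracer, at 1340 ± 671 and 296 ± 120. LECT2 (ENSDARG00000090889), which codes for a secreted chemotactic factor, rose by 5.88 (SE 0.983, adjusted p = 0.00536) and TCIM (ENSDARG00000076858) by 5.27 (SE 0.922, adjusted p = 0.00744). PHGDH, the first enzyme of serine synthesis, rose by 3.66 (SE 0.692, adjusted p = 0.0169). The immediate-early gene fosaa fell by 4.84 (SE 0.892, adjusted p = 0.0147). FGF20 (ENSDARG00000007356), a growth factor gene, fell by 3.64 (SE 0.727, adjusted p = 0.0288), and ATP1B1 (ENSDARG00000076833), a sodium pump subunit gene, by 2.53 (SE 0.443, adjusted p = 0.00744).

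The 80 ribosomal protein genes had a median of 0.69, with 0 past the test over all genes and 1 higher adjusted over the list alone (camera adjusted p = 3.88e-12; adjusted p = 0.445 with an estimated correlation). The 13 mitochondrial genome genes had a median of 1.1, with 0 and 10 (camera adjusted p = 1.63e-10; adjusted p = 0.251 with an estimated correlation). Of 20 heat shock and chaperone genes 18 had a negative fold change, the median was -0.66 and 0 passed by either count (camera adjusted p = 3.13e-05; adjusted p = 0.251 with an estimated correlation). Nuclear genes of oxidative phosphorylation (109 genes, median -0.26; camera adjusted p = 7.75e-07) and growth cone and axon cytoskeleton genes (39 genes, median -0.30; camera adjusted p = 0.00342) had 0 members past the test over all genes. Adjusted over the list alone 0 and 1 were higher, and the adjusted p was 0.494 and 0.345 with an estimated correlation. The growth cone call was lost without Dcon replicate 4 (0.051) or D8W replicate 1 (0.062). Lists of other cell types passed here too. The median was 1.075 for 17 oligodendrocyte and Schwann cell markers (camera adjusted p = 0.0424; adjusted p = 0.539 with an estimated correlation). It was 1.47 for 19 astroglia and ependymal, 0.71 for 15 endothelial and mural cell and 0.73 for 18 fibroblast and meningeal markers (camera adjusted p = 0.00191, 0.0112 and 0.0137; adjusted p = 0.392 for each with an estimated correlation). In these 4 lists S100B alone passed, over all genes (adjusted p = 0.0455) and adjusted over the list alone. Its call over all genes held only without Dcon replicate 5 or D8W replicate 3 or 4 (up to 0.154), and was lost in 8 of 10 other alternatives (up to 0.547). The oligodendrocyte call was lost without Dcon replicate 1 or 4 or D8W replicate 1, 2 or 3 (up to 0.448) and in 4 other alternatives, with array weights the most (0.487), and the fibroblast call without Dcon replicate 2 or D8W replicate 1 (up to 0.394). The astroglia and endothelial calls were lost without D8W replicate 1 (0.0982 and 0.126). The level of gap43 was 285 ± 361 FPKM (-0.92, SE 0.617, adjusted p = 0.617). That of ATF3 was 107 ± 66.9 (-0.17, SE 0.525, adjusted p = 0.946). For ATF3 the sign changed without Dcon replicate 1 (0.28), without D8W replicate 4 (0.07) and with array weights (0.12).

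In all, 9 genes rose and 5 fell at 8 weeks, and 2425 had an unadjusted p under 0.05. The split was 6 and 13 with FPKM as deposited and 13 and 10 after quantile normalization. The count was 5 without Dcon replicate 4, 9 without Dcon replicate 2, 7 without D8W replicate 6, 33 and 30 without D8W replicates 3 and 4, and 47 without both libraries with fewest genes. The calls of icn, s100a10b, LECT2 and TCIM held whichever library was left out, and that of LECT2 in the other alternatives as well. icn lost its call with only the 2 groups compared (0.124), and s100a10b and TCIM lost theirs with a replicate block (0.127 and 0.126) and with voom (0.229 and 0.0711). All of PHGDH, fosaa, FGF20 and ATP1B1 lost theirs without Dcon replicate 4. PHGDH also lost it without Dcon replicate 1 or 2 or D8W replicate 1 or 6, fosaa without Dcon replicate 3 or D8W replicate 6, and FGF20 without Dcon replicate 1, 2 or 3 or D8W replicate 2 or 6. Their adjusted p rose to at most 0.0744 for PHGDH, 0.0698 for fosaa, 0.108 for FGF20 and 0.0638 for ATP1B1. In the other alternatives PHGDH lost its call in 2 of 10, fosaa in 3 of 10 and FGF20 in 4 of 10 (up to 0.334, 0.123 and 0.364), and ATP1B1 in 0 of 9. Both time points share the Dcon libraries. Their lists had 7 risen genes and 1 fallen gene in common, where independent lists would share 0.044 and 0.015 and unchanged groups against the same controls shared 0.01. Unchanged groups give few calls of any kind, so their shared count cannot show what the shared controls add. With the controls split between the comparisons, which leaves fewer in each, the means were 1.1 and 0. Across genes, which are not independent replicates, the fold changes correlated at r = 0.618, against 0.515 ± 0.092 (SD) in unchanged groups. This r alone does not show agreement beyond the shared controls. Their covariance was 0.469, against 0.249 in unchanged groups. With split controls, where the comparisons share no library, r was 0.241 and the covariance 0.241. That part cannot come from control libraries used in both comparisons. Unchanged groups were not simulated with split controls, and what this part reflects was not tested.

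Between the times (D8W against D3W) 6 genes rose and 3 fell, and 2071 had an unadjusted p under 0.05. NEUROD1, a neuronal differentiation factor gene, rose by 3.88 (SE 0.71, adjusted p = 0.0154), from 1.89 ± 2.57 FPKM in D3W (n = 5) to 44.1 ± 40.3 in D8W (n = 6). A 5S_rRNA copy (ENSDARG00000108569) rose by 4.69 (SE 0.759, adjusted p = 0.00293), but 5S genes are near-identical copies, so the assignment of their fragments is uncertain. The ribosomal protein list had a median of -0.63 and the nuclear oxidative phosphorylation list one of -0.45 (camera adjusted p = 3.17e-19 and 1.45e-06), with 0 members past the test over all genes or adjusted over the list alone and an adjusted p = 0.96 for each with an estimated correlation. The first call was lost without both libraries with fewest genes (0.812), the other without D8W replicate 1 (0.0903) and after quantile normalization (0.376). The call of NEUROD1 was lost without D3W replicate 3 or 5 or D8W replicate 2 or 3 (adjusted p up to 0.117) and in 7 of 10 other alternatives (up to 0.73). That of the 5S_rRNA copy was lost with only the 2 groups compared and with a replicate block (up to 0.712). The count of 9 became 3 without D8W replicate 2, 4 without D3W replicate 5 and 49 without D3W replicate 2, and its split was 4 and 1 with FPKM as deposited and after quantile normalization.

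In neurons without tracer the same question compares G cells after injury (n = 5 at each time) with Gcon (n = 6). The sodium channel gene scn4ab was listed at 0 in all 6 Gcon libraries and stood at 4.60 to 127 FPKM in G3W and 6.56 to 45.2 in G8W. Its difference passed at both times (adjusted p = 0.000666 and 0.0172), but at 8 weeks not without G8W replicate 2 (0.0903), and with a replicate block at neither time (0.0598 and 0.372). TCIM (ENSDARG00000076858) rose by 4.66 and 4.83 (SE 0.922 for each, adjusted p = 0.0294 and 0.0319). RGCC, a cell cycle regulator gene, rose by 5.10 at 3 weeks (SE 1.05, adjusted p = 0.0423) and CYP26B1, an enzyme that degrades retinoic acid, by 3.39 at 8 weeks (SE 0.673, adjusted p = 0.0434). The naming rule took each at 1 time, but both had higher means than Gcon at both times. RGCC was at 12.9 ± 21.3 FPKM in Gcon, 239 ± 134 in G3W and 194 ± 188 in G8W. CYP26B1 was at 0.0788 ± 0.124, 31.9 ± 30.1 and 17.7 ± 14.8. An early or late response is thus not shown for either. DGAT2, an enzyme of triglyceride synthesis, fell by 2.24 at both times (SE 0.441, adjusted p = 0.0294 and 0.0433).

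The 80 ribosomal protein genes had a median of 1.04 at 3 weeks, with 0 past the test over all genes and 60 higher adjusted over the list alone. At 8 weeks it was 0.79, with 0 and 0 (camera adjusted p = 1.45e-36 and 4.27e-26; adjusted p = 0.297 and 0.243 with an estimated correlation). Glutamate receptor genes, 41 tested, had medians of -0.29 and -0.37, and this list held with an estimated correlation (adjusted p = 0.0485 and 0.0361). It had 0 members past the test over all genes and 1 lower adjusted over the list alone at each time. Microglia and macrophage markers, 26 tested, had medians of 0.75 and 1.35, with 0 past the test over all genes and 0 and 7 higher adjusted over the list alone (camera adjusted p = 0.043 and 7.57e-10; adjusted p = 0.752 and 0.243 with an estimated correlation). The 3-week microglia call was lost without Gcon replicate 2, 3, 5 or 6 or G3W replicate 4 or 5 (adjusted p up to 0.453), and also with FPKM as deposited (0.0677), with array weights (0.0868) and without the D3W libraries with fewest genes (0.0553). Synaptic vesicle genes had medians of -0.35 and -0.38 and 0 members past either test (camera adjusted p = 2.71e-05 and 9.61e-05; adjusted p = 0.29 and 0.243 with an estimated correlation). The mitochondrial genome genes at 8 weeks had a median of 0.87, with 0 past the test over all genes and 8 higher adjusted over the list alone (camera adjusted p = 7.57e-10; adjusted p = 0.243 with an estimated correlation).

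At 3 weeks 18 genes rose and 3 fell and 1581 had an unadjusted p under 0.05; at 8 weeks 6 rose and 1 fell, with 1417. After quantile normalization the 3-week split was 15 and 5. The 3-week count was 8 without Gcon replicate 6 or G3W replicate 1, 9 without Gcon replicate 1, 10 without Gcon replicate 3 or 5, and 13 without G3W replicate 2 or 4. It was 11 without the D3W libraries with fewest genes, which share the estimate of spread. The 8-week count fell to 2 without G8W replicate 2, 3 without Gcon replicate 4 or 6, and 4 without any other G8W library. TCIM lost its call at both times without Gcon replicate 1, 4, 5 or 6 or replicate 1, 2, 4 or 5 of the injured group (adjusted p up to 0.118 and 0.114). RGCC lost it without Gcon replicate 1, 2, 5 or 6 or G3W replicate 1, 2, 4 or 5 (up to 0.14). CYP26B1 lost it without any library but G8W replicate 5 (up to 0.194). DGAT2 lost it at 3 weeks without Gcon replicate 1, 2 or 3 or G3W replicate 1, 2, 3 or 4 (up to 0.101), and at 8 weeks without any library but Gcon replicates 5 and 6 (up to 0.128). Of 10 other alternatives TCIM lost its call in 4 at each time (up to 0.176 and 0.748), RGCC in 5 (up to 0.202), CYP26B1 in 5 (up to 0.764), and DGAT2 in 4 at 3 weeks and 8 at 8 weeks (up to 0.367 and 0.764). The 2 lists shared 5 risen genes and 1 fallen gene, where independent lists would share 0.005 and 0. Unchanged groups against the same controls shared 0, but they give few calls of any kind, so this cannot show what shared controls add. Split controls, with fewer libraries in each comparison, gave 1 and 0. Their fold changes correlated across genes at r = 0.631, against 0.476 ± 0.104 (SD) in unchanged groups. Here too this r alone does not show agreement beyond the shared controls. Their covariance was 0.311, against 0.211 in unchanged groups. With split controls, where no library is shared, r was 0.168 and the covariance 0.114. That part cannot come from control libraries used in both comparisons, but it has no simulated baseline. Between the times (G8W against G3W) 1 gene assembled outside the annotation (Novel01966) fell by 2.44 (SE 0.404, adjusted p = 0.0129) and 714 had an unadjusted p under 0.05. It was lost, with a count of 0, without G3W replicate 4 or G8W replicate 1, 4 or 5 (adjusted p up to 0.0652), and it was lost in 4 of 10 other alternatives (up to 0.895). The count was 2 without G3W replicate 1 or 3 or G8W replicate 2 or 3, and 3 without G3W replicate 2 or 5. The mitochondrial genome list had a median of 0.73 and the microglia list one of 0.80 between the times (camera adjusted p = 6.11e-12 and 9.75e-05), with 0 members past either test (adjusted p = 0.636 and 0.918 with an estimated correlation).

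Before injury the tracer itself separated neurons (Dcon, n = 5, against Gcon, n = 6). nefla, a neurofilament gene, was higher by 4.48 (SE 0.838, adjusted p = 0.0102), at 120 ± 32.7 FPKM in Dcon and 11.6 ± 15.7 in Gcon. The neurotensin receptor gene NTSR1 was lower by a log2 fold change of -5.14 (SE 0.831, adjusted p = 0.00143), at 6.48 ± 14.3 FPKM in Dcon and 137 ± 90.8 in Gcon. The kinase gene hunk was lower by -4.41 (SE 0.652, adjusted p = 0.000481). The glutamate receptor genes GRIA1 (ENSDARG00000032714) and GRM3 were lower by -2.94 (SE 0.542, adjusted p = 0.00883) and -1.99 (SE 0.352, adjusted p = 0.0052). These 5 calls held whichever library was left out, but with a replicate block all 5 were lost. That of nefla was also lost with voom, and those of GRIA1 and GRM3 with only the 2 groups compared (adjusted p up to 0.108 for nefla, NTSR1 and hunk, 0.233 for GRIA1 and 0.338 for GRM3). SOX11 (ENSDARG00000077811), a transcription factor gene of immature neurons, was at -2.57 (SE 0.537, adjusted p = 0.0249) and icn at -4.67 (SE 1.01, adjusted p = 0.0362). SOX11 was lost without Gcon replicate 2 or 3 or Dcon replicate 2, 3, 4 or 5 (adjusted p up to 0.0866), and icn without Gcon replicate 1, 2, 3 or 4 or Dcon replicate 1, 2 or 4 (up to 0.121). In other alternatives SOX11 was lost in 2 of 10 (up to 0.233) and icn in 6 of 9 (up to 0.283).

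All 7 neurofilament genes were higher in Dcon, with a median of 2.35, 1 risen over all genes and 5 adjusted over the list alone. The list held with an estimated correlation (camera adjusted p = 9.81e-09; adjusted p = 0.0131 with an estimated correlation). The 13 mitochondrial genome genes had a median of 1.16, with 0 past the test over all genes and 12 higher adjusted over the list alone (camera adjusted p = 1.93e-16; adjusted p = 0.125 with an estimated correlation). The 109 nuclear oxidative phosphorylation genes had a median of 0.83, with 1 risen and 17 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.25e-26; adjusted p = 0.256 with an estimated correlation). The 1 risen gene, ATP5F1A (adjusted p = 0.0479), passed in single-library fits only without Gcon replicate 5 or 6 (up to 0.153) and was lost in 6 of 9 other alternatives (up to 0.228). Microglia markers had a median of 1.24 (0 past the test over all genes, 4 higher adjusted over the list alone; camera adjusted p = 3.45e-07). Oligodendrocyte and Schwann cell markers had one of -0.85 (0 past the test over all genes, 1 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0269). The adjusted p was 0.563 and 0.598 with an estimated correlation. The latter call was lost without Gcon replicate 2, 3 or 5 or Dcon replicate 1 or 4 (up to 0.342) and with array weights (0.603). In all, 19 genes were higher and 46 lower, and 2398 had an unadjusted p under 0.05. The split was 8 and 149 with FPKM as deposited and 8 and 37 after quantile normalization. The count was 37, 23, 39 and 34 without Gcon replicates 1 to 4, 23, 36 and 20 without Dcon replicates 1, 2 and 4, and 124 without the D3W libraries with fewest genes.

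After injury D was compared with G. G cells lack tracer, as the uninjured Gcon cells do, so they need not be neurons that failed to regrow an axon. At 3 weeks (D3W against G3W, n = 5 each) the neuronal differentiation factor genes NEUROD1 and NEUROD4 were lower by log2 fold changes of -5.72 (SE 0.741, adjusted p = 2.7e-05) and -5.64 (SE 0.631, adjusted p = 2.33e-06). NEUROD1 was at 1.89 ± 2.57 FPKM in D3W and 158 ± 44.2 in G3W. FEV, a transcription factor gene of serotonergic neurons, was lower by -5.67 (SE 0.959, adjusted p = 0.00123) and the urocortin gene UCN3 by -5.60 (SE 0.981, adjusted p = 0.00173). The GABA receptor gene gabrr3b was lower by -5.34 (SE 0.879, adjusted p = 0.000925), NTSR1 by -5.18 (SE 0.868, adjusted p = 0.00115) and hunk by -4.99 (SE 0.680, adjusted p = 6.52e-05). The sodium pump gene atp1a3b was higher in D3W by 4.15 (SE 0.675, adjusted p = 0.000925), at 360 ± 305 FPKM against 29.0 ± 15.5. The elongation factor gene eef1a2 was higher by 3.85 (SE 0.824, adjusted p = 0.0113). These 9 calls held whichever library was left out. With the number of detected genes as a covariate FEV, UCN3, gabrr3b and eef1a2 lost theirs (adjusted p = 0.0568, 0.0891, 0.0666 and 0.0866). Without the 2 D3W libraries with fewest genes UCN3 and eef1a2 did, and eef1a2 also with a pseudocount of 0.1 and with a replicate block (no higher than with the covariate), and atp1a3b with voom (0.253).

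All 13 mitochondrial genome genes rose over all genes and adjusted over the list alone, with a median of 1.93 (camera adjusted p = 3.08e-36; adjusted p = 0.00635 with an estimated correlation). MT-ND5, for example, was higher by 2.18 (SE 0.369, adjusted p = 0.00125), though not called with a replicate block (0.0681). MT-ND2, MT-ATP6 and MT-ND4 lost their calls with the block, with detected genes as a covariate and without the 2 libraries with fewest genes (up to 0.127, 0.091 and 0.104). The 7 V2a and glutamatergic identity genes had a median of -2.32, with 2 fallen and 4 adjusted over the list alone (camera adjusted p = 0.00235; adjusted p = 0.209 with an estimated correlation). SOX14 (ENSDARG00000070929) fell by 3.16 (SE 0.663, adjusted p = 0.00988) whichever library was left out, but did not pass with the covariate of detected genes (0.146), with only the 2 groups compared (0.127) or with a block (0.108). Markers of other cells passed as lists. The median was 0.65 for 9 motor neuron and 0.47 for 17 oligodendrocyte and Schwann cell markers (camera adjusted p = 0.0211 and 0.0337; adjusted p = 0.46 and 0.52 with an estimated correlation). They had 0 members past the test over all genes and 1 and 2 higher adjusted over the list alone. The motor neuron call was lost without G3W replicate 4 (0.0531) or D3W replicate 2 (0.125), after quantile normalization (0.129) and with no filter, where its median was 0.004 (0.0657). The oligodendrocyte call was lost without G3W replicate 2 or 3 or D3W replicate 2, 3 or 4 (up to 0.248), after quantile normalization (0.487), with no filter (0.0636) and without the 2 libraries with fewest genes (0.218), and its median was -0.17 with FPKM as deposited. SOX11 (ENSDARG00000077811) was at -2.25 (SE 0.561, adjusted p = 0.0349), a call lost in 7 of 10 single-library fits (up to 0.105), held only without G3W replicate 4 or D3W replicate 4 or 5, and lost in 5 of 10 other alternatives (up to 0.202). Nuclear oxidative phosphorylation genes had a median of 0.89 (camera adjusted p = 4.35e-26) and neurofilament genes of 1.53 (camera adjusted p = 0.000307). In each 0 passed the test over all genes, and 0 and 3 higher adjusted over the list alone (adjusted p = 0.209 and 0.163 with an estimated correlation). The ribosomal protein genes had a median of 0.04 that turned to -0.59 with FPKM as deposited and -0.49 after quantile normalization. The glutamate vesicle transporter genes SLC17A6 (ENSDARG00000041150 and ENSDARG00000001127) were at 0.44 and -0.60 (adjusted p = 0.763 and 0.764), gap43 at 0.81 (adjusted p = 0.623) and ATF3 at 1.62 (adjusted p = 0.155). The first SLC17A6 gene was at -0.18 with FPKM as deposited and the other at 0.03 without D3W replicate 5.

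In all, 44 genes were higher and 246 lower in D3W, and 3024 had an unadjusted p under 0.05. The split was 25 and 725 with FPKM as deposited and 34 and 168 after quantile normalization, and 13 and 43 without the 2 libraries with fewest genes, both of D3W. The count was 161, 177, 145, 178 and 190 without G3W replicates 1 to 5, and 156, 188 and 147 without D3W replicates 3 to 5. It was 28 with the number of detected genes as a covariate. Of the genes called here, 5 higher and 20 lower genes were also called in Dcon against Gcon, which shares no library, where independent lists would share 0.037 and 0.502. Both lists use the same spread estimate per gene, from all 32 libraries. They are therefore not independent, and the overlap without a common difference may be larger than these values.

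**Figure D4:**
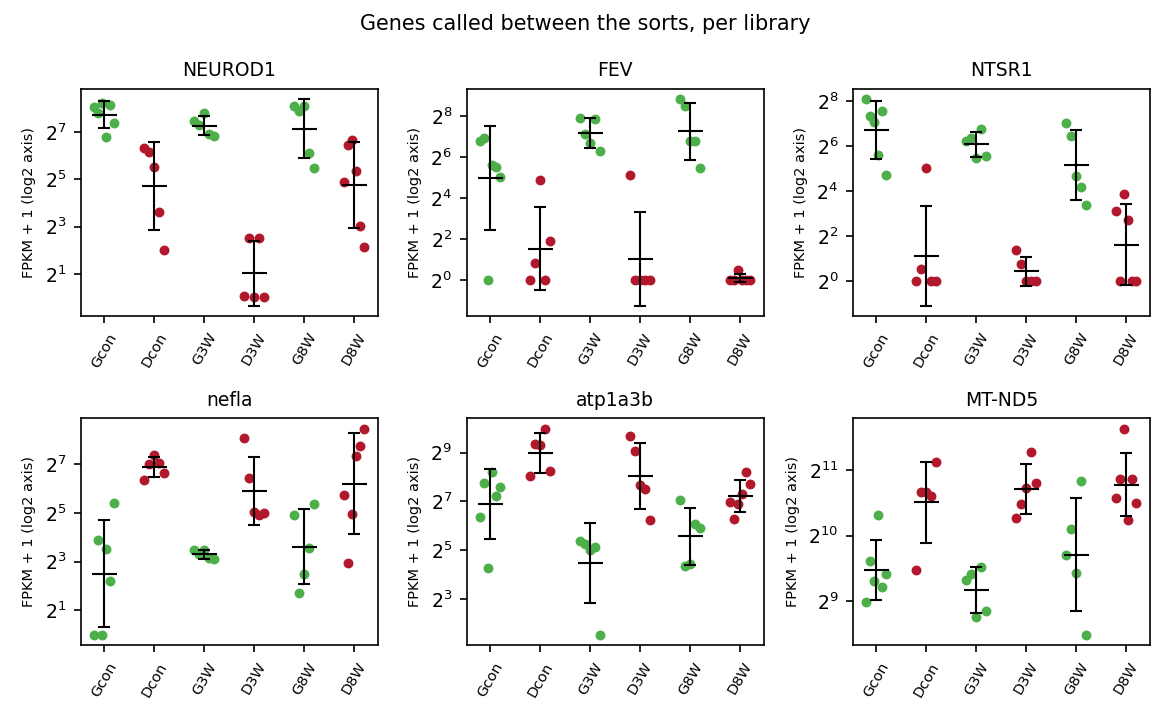
Each point is 1 library (green G, red D), with FPKM + 1 on a log2 axis; bars give the mean and SD of log2(FPKM + 1) per group, n = 5 or 6. The NEUROD1 panel shows D3W libraries at 0 to 4.79 FPKM and G3W libraries at 114 to 221.

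At 8 weeks (D8W, n = 6, against G8W, n = 5) FEV was lower by a log2 fold change of -6.84 (SE 0.918, adjusted p = 0.000178), at 0.068 ± 0.166 FPKM in D8W and 212 ± 178 in G8W. UCN3 was lower by -6.25 (SE 0.939, adjusted p = 0.000666) and NEUROD4 by -4.18 (SE 0.604, adjusted p = 0.000441), whichever library was left out, though NEUROD4 did not pass with a replicate block (0.101). TPH2, the enzyme that starts serotonin synthesis in neurons, was lower by -5.22 (SE 0.99, adjusted p = 0.0142), and the position genes HOXA5 and hoxb6b by -3.86 (SE 0.731, adjusted p = 0.0142) and -3.82 (SE 0.724, adjusted p = 0.0142). All 3 of the latter calls were lost without D8W replicate 4. TPH2 was also lost without G8W replicate 1 or 2 or D8W replicate 5 (adjusted p up to 0.0909), HOXA5 without G8W replicate 1 or 5 or D8W replicate 5 (up to 0.0672), and hoxb6b without G8W replicate 3 or 5 or D8W replicate 6 (up to 0.0676). In 10 other alternatives TPH2 lost its call in 5 and HOXA5 and hoxb6b in 6 each (up to 0.111, 0.125 and 0.201). The mitochondrial genome genes had a median of 1.32, with 0 past the test over all genes and 12 higher adjusted over the list alone, and the neurofilament genes one of 1.84, with 0 and 4. Both lists held with an estimated correlation (adjusted p = 0.0309 for each). The V2a identity genes had a median of -1.19 and 0 members past either test (camera adjusted p = 0.0441; adjusted p = 0.881 with an estimated correlation). That call was lost without G8W replicate 1, 2 or 3 or D8W replicate 1, 5 or 6 (up to 0.249), with a pseudocount of 0.1 (0.138), with no filter (0.128) and with array weights (0.116). Inhibitory neuron markers (13 genes) had a median of -0.825 and fibroblast and meningeal markers (18 genes) one of 0.35 (camera adjusted p = 0.0207 and 0.0441; adjusted p = 0.881 for each with an estimated correlation). They had 0 members past the test over all genes, and 2 and 0 lower adjusted over the list alone. The first call was lost without G8W replicate 2 or D8W replicate 2 or 3 (up to 0.132), the other without G8W replicate 2, 3 or 4 or D8W replicate 1 or 5 (up to 0.734) and with a pseudocount of 0.1 (0.138). In all, 1 gene was higher and 14 lower, and 1575 had an unadjusted p under 0.05. The count was 7 without D8W replicate 4 or 5, 8 without D8W replicate 6 or G8W replicate 1 or 3, 26 without G8W replicate 4, and 28 without the D3W libraries with fewest genes. Between 3 and 8 weeks 1 higher gene and 7 lower genes were shared, where independent lists would share 0.002 and 0.153. These lists also use the same spread estimate per gene, so they are not independent.

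**Figure D5:**
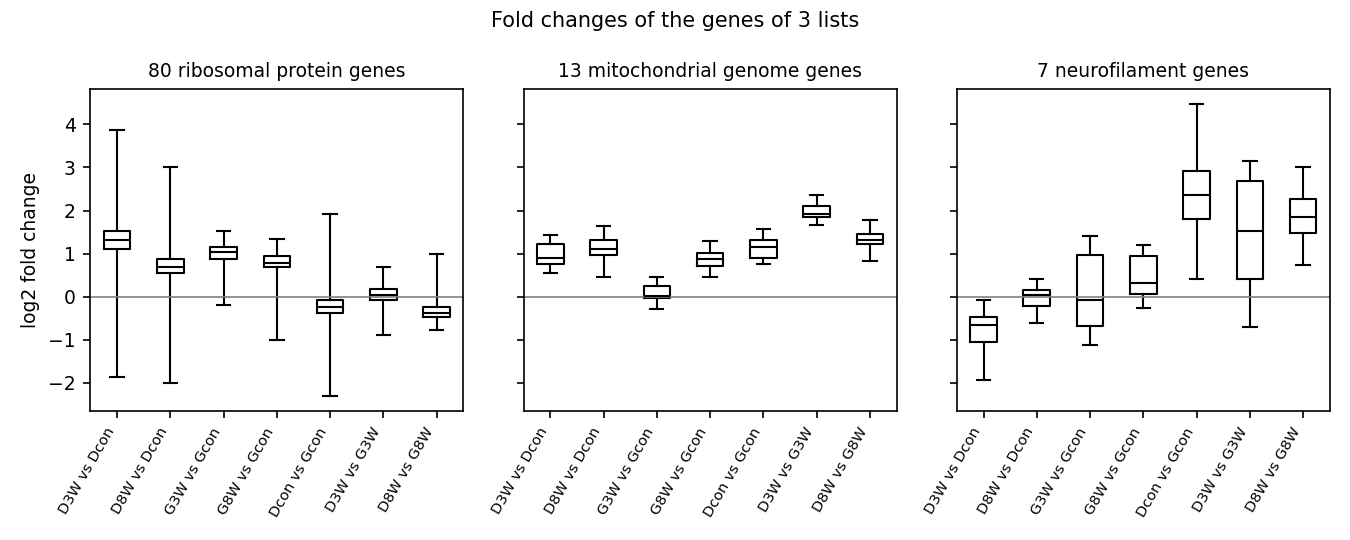
Boxes give the quartiles and median of log2 fold changes of the genes of each list (80 ribosomal protein, 13 mitochondrial genome and 7 neurofilament genes) in 7 comparisons, with whiskers to the lowest and highest gene. For mitochondrial genome genes the median was 1.93 in D3W against G3W and 1.32 in D8W against G8W.

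Whether injury changed D and G neurons differently was tested as an interaction. At 3 weeks 1 gene passed, a 5S_rRNA copy (ENSDARG00000108569) at -6.32 (SE 1.1, adjusted p = 0.0317), and 1267 had an unadjusted p under 0.05. That call was lost in 15 of 21 single-library fits (adjusted p up to 0.136), held only without Gcon replicate 1 or 6, Dcon replicate 3 or G3W replicate 3, 4 or 5. It was also lost in 4 of 9 other alternatives (up to 0.169). The count was 2 without G3W replicate 4, 1 without Gcon replicate 1 or 6, Dcon replicate 3 or 4 or G3W replicate 3 or 5, and 0 without any of the other 14 libraries. limma voom called 2. At 8 weeks limma called 0 genes, with 1027 at an unadjusted p under 0.05, and limma voom on recovered fragments also called 0. In other fits 1 gene passed without Dcon replicate 1 or 4, and 2 with array weights. Genes that passed in one sort and not in the other are not shown to differ between the sorts. The mitochondrial genome list differed at 3 weeks (median 0.84, camera adjusted p = 6.87e-07) and the microglia list at both times (median -1.36 and -1.54, camera adjusted p = 0.00697 and 2.2e-06). They had 0 members past either test and an adjusted p = 0.691, 0.83 and 0.857 with an estimated correlation. The mitochondrial genome call was lost after quantile normalization (0.164), and the 3-week microglia call without Gcon replicate 2 or 3, Dcon replicate 4 or G3W replicate 4 (up to 0.147).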

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

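The splits of the libraries and the fit without the 2 libraries with fewest genes had their reading set before their results were seen; the tests of detection, scaling, neuron share, skin cells and astroglia share were chosen after the results they measure were seen.

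Single libraries lay far from the others of their group in 19 of 101 groups of values tested. Chance would give about 1 in 20, or 5, for normally distributed values. FPKM values are skewed and often 0, so that rate is not a firm baseline. The 13 genes tested this way were picked after their values were seen. D8W replicate 2 had 9.419 M inferred fragments (others 17.0 to 19.05), D8W replicate 1 had 18220 genes at 1 FPKM or more (others 11900 to 13790), and in Gcon replicate 3 the top gene took 17.0% of FPKM (others 8.91 to 11.85). In FPKM, Dcon replicate 5 stood out for s100a10b at 44.01 (others up to 10.26), S100B at 59.1 (up to 6.446) and scn4ab at 0.4984 (others listed at 0). Dcon replicate 3 stood out for FEV at 28.16 (up to 2.709) and NTSR1 at 31.99 (up to 0.4359), and Dcon replicate 1 for ATF3 at 516.7 (69.99 to 161.1). FEV was 33.11 in D3W replicate 1 and 0.4077 in D8W replicate 3, where the others were listed at 0. nefla was 41.59 in Gcon replicate 6 (up to 13.79) and 271 in D3W replicate 1 (28.91 to 84.98), and atp1a3b was 1.904 in G3W replicate 5 (31.66 to 40.83). RGCC was 55.04 in Gcon replicate 3 (up to 14.44), 520.4 in G8W replicate 2 (48.22 to 161.6) and 569.9 in D8W replicate 1 (1.779 to 214.5). gap43 was 993.8 in D8W replicate 4 (13.77 to 282.9) and CYP26B1 84.38 in G3W replicate 5 (8.071 to 26.84).

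The change after injury differed between D and G cells in the interaction test for 1 gene at 3 weeks, a 5S_rRNA copy (ENSDARG00000108569), at -6.322. Lists differed at the preset correlation, though at an estimated correlation their adjusted p was 0.691 to 0.857. At 3 weeks the list medians were 0.261 for ribosomal proteins (0.844 with an estimated correlation), 0.838 for the mitochondrial genome, 0.506 for the cell cycle, -1.363 for microglia, 1.814 for oligodendrocytes and Schwann cells, 0.649 for astroglia, 1.248 for motor neurons and 0.652 for endothelial cells. At 8 weeks they were -0.411 for nuclear oxidative phosphorylation genes, -0.684 for heat shock genes and -1.539 for microglia. The ribosomal median at 3 weeks was -0.072 with FPKM as deposited, so its direction is not settled. Leaving out single libraries ended several of the 3-week calls. The ribosomal call was lost without Dcon replicate 2, G3W replicate 5 or D3W replicate 5 (adjusted p up to 0.866) and the cell cycle one without Gcon replicate 3, Dcon replicate 2 or 3 or D3W replicate 4 (up to 0.119). The astroglia call was lost without Dcon replicate 2 or D3W replicate 5 (up to 0.072) and the motor neuron one without Dcon replicate 1 or 5, G3W replicate 4 or D3W replicate 2 (up to 0.129). The endothelial call was lost without Gcon replicate 1 or 2, Dcon replicate 1, 2 or 3, G3W replicate 1, 3 or 5 or D3W replicate 4 or 5 (up to 0.356). The microglia call was lost without Gcon replicate 2 or 3, Dcon replicate 4 or G3W replicate 4 (up to 0.147). At 8 weeks the oxidative phosphorylation call was lost without G8W replicate 5 (0.282).

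Each comparison was refitted in 100 splits of its own libraries into groups of the same sizes, the real split included. Given below are the real count, the highest count of another split and the number of splits as large, the real one included. No other split reached the real count for D3W against Dcon (178 and 143, 1 split) or G3W against Gcon (21 and 5, 1 split). The same held for D3W against G3W (290 and 10, 1 split) and Dcon against Gcon (65 and 14, 1 split). This argues against chance for these counts, as far as 100 splits can show. Another split called as many genes or more for D8W against Dcon (14 and 36, 2 splits) and G8W against Gcon (7 and 10, 2 splits). So it was for D8W against G8W (15 and 15, 2 splits) and the 3-week interaction (1 and 1, 4 splits). Chance is less likely there but is not excluded, since each comparison was read alone. Nor can it be excluded for D8W against D3W (9 and 85, 13 splits) or G8W against G3W (1 and 19, 38 splits). In the 8-week interaction (0 and 7; 100 splits) the real count of 0 fixed the outcome, so its splits decide nothing. In D8W against D3W 3 splits called 30 to 85 genes, several times the real count, which points to a structure of the samples. Other splits of D3W against Dcon also called many genes, 143, 64 and 40 in the highest. Its count of 178 may therefore carry such a structure too. In D8W against Dcon 1 split called 36 and the others 9 at most, and in G8W against G3W 1 called 19 and the others 3 at most. What lies behind these splits was not tested, and single outlying libraries or splits that keep part of the real grouping were not told apart.

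Most genes called between D3W and G3W were lower in D3W, 246 of 290. Scaling of the libraries as the whole cause is argued against, since 83.2% of the calls were lower after quantile normalization, a method that sets the same distribution in every library. Fewer genes detected in D3W stays open: with the number of detected genes as a covariate the median of the 246 genes went from -2.596 to -2.169, while their median SE rose from 0.611 to 0.711 and 20 stayed called lower. The covariate goes partly with the group and the genes were chosen for the pattern, so lower detection and a difference between the cells cannot be told apart. The design's biological difference, neurons with a regrown axon against neurons without tracer, is untested beside it. Of the called genes 5 higher and 20 lower ones were also called in Dcon against Gcon, which differ in tracer without injury. Dcon also had fewer genes at 1 FPKM or more than Gcon (12624 ± 1481 against 14670 ± 2466). The overlap therefore does not tell lower detection from a difference between the cells.

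The V2a and glutamatergic identity list was lower in D3W than in G3W by its median, -2.32 with quartiles of -2.45 and -1.29. Of its 7 members 2 passed over all genes and SLC17A6 (ENSDARG00000041150) was at 0.442, and the list did not pass with an estimated correlation (adjusted p = 0.209). A smaller share of neurons in D3W is argued against, since the synaptic vesicle list had a median of 0.081 with quartiles of -0.63 and 0.76, above the upper quartile of the V2a list. The 2 D3W libraries with fewest genes stay open as a part of the cause: without them the median was -1.328. Other neurons in either sort stay open, with a median of 0.647 for motor neuron markers, and lower V2a gene expression in neurons with a regrown axon is untested.

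The S100 family genes icn and s100a10b were higher in D3W than in Dcon. They were also present in cells without tracer, at 1970 ± 1370 and 328 ± 165 FPKM in G3W. Skin epithelial cells, in which fish express S100 genes, are argued against as the source, since krt4, krt5 and cyt1 reached 1.49 FPKM at most in a D3W library where icn was at least 925. Of 17 matched skin markers, ANXA1 ran with the pattern, at 0.41 ± 0.714 FPKM (SD) in Dcon and 29.7 ± 16.5 in D3W. So did the mean of epcam, at 0.19 ± 0.426 and 1.36 ± 2, and both were far below icn. The mean of krt94 was higher too, at 1.31 ± 2.16 and 4.5 ± 10.1. Its highest value in any library was 22.49 FPKM, so with that SD it shows no rise across the D3W libraries. The sort for the green reporter and tracer is meant to leave out such cells, but its purity was not tested. For a larger share of astroglia and ependymal cells, the upper quartile of that list was 2.451 against a change of 7.03 for s100a10b. This met the mark set against such a share as the whole cause. The mark cannot decide, since how far a marker moves with added cells depends on its level in Dcon. S100B is a member of that list and passed over all genes, at 13.4 ± 25.7 FPKM in Dcon and 207 ± 68.7 in D3W. In all, 6 members were higher adjusted over the list alone. A larger share of such cells thus stays open. A response of the neurons to injury is a hypothesis that these tests leave open.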

How the results depend on the processing

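The covariate of detected genes, the fit without the 2 libraries with fewest genes and limma voom were chosen after seeing the data; the other alternatives were fixed before the data were examined. Counts moved by over 1.5 times in 140 of 258 refits. Named genes kept direction and side of the threshold in 2336, lost a call in 873, gained one in 11 and changed sign in 40; those 40 are all genes fixed in advance that did not pass. Lists stayed in 1261, were lost in 246 and changed sign in 22. The fixed genes changed sign in 115 of 2119 fits over all 11 comparisons, with an adjusted p of at least 0.715. After that was seen, their fold changes were kept to 4 comparisons, D3W and D8W against Dcon and D against G after injury, and are left out elsewhere except for SOX11 (ENSDARG00000077811), which passed in Dcon against Gcon. Where a value below changed, the cause was not tested, except that fits of 2 groups or of fewer libraries have fewer samples. Depth limits low genes most. D3W replicates 3 and 5 had 7755 and 8710 genes at 1 FPKM or more from 18.1 and 15.6 M inferred fragments, while D8W replicate 2 had 11897 from 9.42 M, so depth is not shown to be why they had few.

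With no filter the counts were 58 for D3W against Dcon, 7 for D8W against Dcon, 4 for D8W against D3W, 8 for G3W and 2 for G8W against Gcon, 6 for D8W against G8W, 35 for Dcon against Gcon and 0 for the 3-week interaction.

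With FPKM as deposited the counts were 5 for D8W against D3W, 38 for G3W against Gcon, 2 for G8W against G3W, 750 for D3W against G3W, 35 for D8W against G8W and 157 for Dcon against Gcon. In D3W against Dcon ATF3 was at -0.124, SLC17A6 (ENSDARG00000041150) at -0.139 and gap43 at -0.029, and this SLC17A6 gene was at -0.019 in D8W against Dcon and -0.176 in D3W against G3W. STMN4 (ENSDARG00000043932) was at -0.033 in D3W against G3W and -0.377 in D8W against G8W, and SOX11 (ENSDARG00000095743) at -0.122 in the latter. List medians in D3W against G3W were -0.364 for immediate-early genes, -0.594 for ribosomal proteins, -0.257 for synaptic vesicle genes and -0.168 for oligodendrocyte markers. In D8W against G8W they were -0.09 for nuclear oxidative phosphorylation and -0.19 for synaptic vesicle genes, in Dcon against Gcon -0.041 for heat shock and -0.063 for synaptic vesicle genes, and for ribosomal proteins in the 3-week interaction -0.072.

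After quantile normalization the counts were 23 for D8W against Dcon, 5 for D8W against D3W and 0 for G8W against G3W. In D3W against Dcon STMN4 (ENSDARG00000030106) was at -0.024, ATF3 at -0.053, SLC17A6 (ENSDARG00000041150) at -0.028 and gap43 at -0.028. The ribosomal median in D3W against G3W was -0.487.

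With array weights the counts were 85 for D3W against Dcon, 3 for D8W against D3W, 112 for G3W and 87 for G8W against Gcon, 16 for G8W against G3W, 23 for D8W against G8W, 147 for Dcon against Gcon and 2 for the 8-week interaction. SLC17A6 (ENSDARG00000041150) was at -0.141 in D3W against Dcon and ATF3 at 0.122 in D8W against Dcon. Medians in D3W against G3W were -0.075 for immediate-early genes and -0.308 for ribosomal proteins, which stood at -0.02 in the 3-week interaction.

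With only the groups compared the counts were 15 for D3W against Dcon, 1 for D8W against D3W, 0 for G8W against G3W, 115 for D3W against G3W, 9 for D8W against G8W and 40 for Dcon against Gcon.

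Replicate numbers did not pair the libraries: 45 same-number pairs correlated at -0.131 to 0.141. With a replicate block, which then costs samples for no pairing, the counts were 15 for D3W against Dcon, 9 for D8W against Dcon, 0 for D8W against D3W, 4 for G3W and 0 for G8W against Gcon, 0 for G8W against G3W, 26 for D3W against G3W, 2 for D8W against G8W and 0 for Dcon against Gcon.

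With detected genes as a covariate the counts were 5 for D8W against D3W, 8 for G3W against Gcon, 28 for D3W against G3W, 6 for D8W against G8W, 38 for Dcon against Gcon and 0 for the 3-week interaction. STMN4 (ENSDARG00000043932) was at -0.006 in D3W against G3W and -0.116 in D8W against G8W.

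Without the 2 libraries with fewest genes the counts were 20 for D3W against Dcon, 47 for D8W against Dcon, 4 for D8W against D3W, 11 for G3W against Gcon, 56 for D3W against G3W, 28 for D8W against G8W, 124 for Dcon against Gcon and 0 for the 3-week interaction. In D3W against Dcon ATF3 was at -0.082 and SOX11 (ENSDARG00000095743) at 0.63. The ribosomal median was -0.522 in D3W against G3W and -0.271 in the 3-week interaction.

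With limma voom the counts were 64 for D8W against Dcon, 102 for G3W and 34 for G8W against Gcon, 0 for G8W against G3W, 437 for D3W against G3W, 317 for Dcon against Gcon and 2 for the 3-week interaction. In D3W against Dcon ATF3 was at -0.019 and SOX11 (ENSDARG00000095743) at 0.193.

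Leaving out each library in turn, the counts ran from 59 to 570 for D3W against Dcon, 5 to 33 for D8W against Dcon, 3 to 49 for D8W against D3W, 8 to 18 for G3W and 2 to 7 for G8W against Gcon, 0 to 3 for G8W against G3W, 145 to 274 for D3W against G3W, 7 to 26 for D8W against G8W, 20 to 93 for Dcon against Gcon, 0 to 2 for the 3-week and 0 to 1 for the 8-week interaction. In D3W against Dcon ATF3 ran from -0.034 to 0.668, SLC17A6 (ENSDARG00000041150) from -0.525 to 0.511 and SOX11 (ENSDARG00000095743) from -0.906 to 0.383. In D8W against Dcon these ran from -0.419 to 0.283, -0.33 to 0.705 and -0.243 to 0.782. In D3W against G3W SLC17A6 (ENSDARG00000001127) ran from -0.986 to 0.033, and medians from -0.303 to 0.413 for ribosomal proteins, -0.054 to 0.27 for synaptic vesicle genes and -0.098 to 0.472 for immediate-early genes. In D8W against G8W the ranges were -0.347 to 0.389 for STMN4 (ENSDARG00000030106), -0.211 to 0.366 for STMN4 (ENSDARG00000043932), -0.02 to 0.659 for SOX11 (ENSDARG00000095743) and -0.707 to 0.513 for gap43. The ribosomal median in the 3-week interaction ran from -0.057 to 0.637.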

Other observations

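The test in this part was chosen after its result was seen. TPH2 and FEV, genes of serotonergic neurons, had higher means in G than in D libraries in each condition. For TPH2 this passed at 8 weeks (adjusted p = 0.0142) but not at 3 weeks (0.0559) or before injury (0.252), and for FEV at 3 and 8 weeks (0.00123 and 0.000178) but not before injury (0.147). TPH2 was at 50.1 ± 46.4 FPKM in Gcon (SD, n = 6) and 4.82 ± 6.99 in Dcon (n = 5), at 96.7 ± 36.2 in G3W and 16.9 ± 31.9 in D3W (n = 5 each), and at 110 ± 109 in G8W (n = 5) and 0.573 ± 0.901 in D8W (n = 6). One hypothesis is that the G sort held some serotonergic neurons. Of 13 tested markers from a list of 14 matched genes, 9 were higher in G in all 3 conditions, fewer than the mark set for the test, which left it open. htr1aa ran the other way, at 2.06, 0.06 and 2.42 in D against G before injury and at 3 and 8 weeks, where it did not pass (adjusted p = 0.428, 0.989 and 0.55). The serotonin transporter gene SLC6A4 was low even in G, at 0.676 ± 1.52 FPKM in Gcon, 4.23 ± 4.68 in G3W and 1.14 ± 2.52 in G8W. Reporter expression in such cells would be 1 way for them to enter the G sort. Expression of these genes in V2a neurons without tracer is another possible account of the 9 markers. These accounts were not told apart here. The sort is meant to leave out cells that lack the reporter, but its purity was not tested.

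Between libraries of 1 group, 70 pairs were compared; 0 were identical, and r across genes, which are not independent replicates, ran from 0.571 to 0.867.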
